A study of Mus musculus with 2 samples.

How the data were processed

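RNA was sequenced from 2 cultured mouse pancreatic cancer cell lines, 1 library per line. Per the labels' protocols, total RNA came from untreated cells grown in serum-containing DMEM, and the libraries were made with a stranded Illumina mRNA kit. The submitters' processing notes name STAR, HTSeq, DESeq2 and the mouse build mm10, without versions or roles. The authors deposited 2 tables with 20346 gene symbols each, in the same order. By their names, one holds the raw counts per gene and the other counts normalized with DESeq2 by the authors.

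The value columns of both tables were left out. Each table has 2 value columns, so 4 columns were not matched to a sample. Their headers are codes that occur in no label of either sample and do not name a genotype. A column was given to a line only where its header matched that line's labels. The order of the columns and the level of any gene, Col1a1 included, were not used to decide which column was the knockout. Neither fold changes nor levels per line were computed for this reason. Sequencing depth per line is not given here, for the same reason.

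The gene symbols of the tables were read with Python 3.11.15 and pandas 2.3.3. They were compared with GENCODE release M21, an annotation of GRCm38, which is the assembly that mm10 names. They were also compared with the RefSeq gene table of GRCm38.p6, once by symbol and once by symbol or synonym. All of these comparisons of symbols were chosen after seeing the data. Gene positions are from GENCODE M21 and count from 1. The design, 30 gene lists and the rule for named genes were fixed before the data were examined. That rule named the targeted gene Col1a1, its partner Col1a2, the genes of the driver alleles (Kras, Trp53 and Pdx1), the genes with the largest ratios between the lines, the leading members of each list and the sex chromosome transcripts. Values of columns not matched to a sample were not used in any step, including quantities that would not depend on which column is which, so only the parts of the rule that need no value were applied. No test was run.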

Results

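The series compared 2 primary cell lines, each grown out of a pancreatic tumour of a genetically engineered mouse. The control line came from a KPPC tumour, in which Pdx1-Cre switches on oncogenic Kras and removes both floxed copies of Trp53 in the pancreatic lineage. The other line came from a tumour of the same model that also carried floxed Col1a1 alleles, so that the cancer cells lose the gene for the alpha-1 chain of type I collagen. The question the design addresses is how the transcriptome of pancreatic cancer cells differs when they lack their own type I collagen. There was 1 library per line, so a difference between the lines would have had no replicate check, and the loss of Col1a1 could not have been separated from other differences between 2 independently derived lines.

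The comparison between the genotypes was not made. The column headers of the deposited count tables are codes that match neither line's labels, and no column was assigned to a genotype. The expression of Col1a1, which was planned as a check of the labels, is not reported for either line, and no gene is described as higher or lower.

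The genes that the comparison is about were all among the 20346 symbols of the tables. Col1a1, which encodes the alpha-1 chain of type I collagen, is a protein-coding gene on chromosome 11 of GRCm38 (mm10), from 94936224 to 94953042 on the plus strand, and its first-numbered transcript in GENCODE M21 has 51 exons. The labels do not say which part of Col1a1 lies between the loxP sites. Col1a2, which encodes the alpha-2 chain that joins a pair of alpha-1 chains in the common form of type I collagen, lies on chromosome 6 from 4504814 to 4541544 on the plus strand, and its first-numbered transcript has 52 exons. Kras, the driver oncogene of the model, lies on chromosome 6 from 145216699 to 145250239 on the minus strand. Trp53, the deleted tumour suppressor, lies on chromosome 11 from 69580359 to 69591873 on the plus strand. Pdx1, a regulator of pancreatic development whose promoter drives Cre in this model, lies on chromosome 5 from 147269959 to 147275848 on the plus strand.

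Of the 20346 symbols, 19246 (94.6%) were gene names in GENCODE M21. The fixed gene lists held 795 distinct members, of which 787 were listed. Some members were fixed with an alternative symbol, such as P3h1 with Lepre1, and either symbol counted as listed. Every member was listed for 25 of the 30 lists, among them the 39 other collagens, the 21 integrins, the 19 laminin and basement membrane genes, the 38 epithelial markers and the 27 mesenchymal genes. Markers of other cells that a tumour-derived culture could hold were listed in full, with 23 fibroblast and stellate, 24 leukocyte, 14 endothelial and 33 acinar and endocrine genes. A listed symbol was not read as a sign that the gene was expressed. Whether the authors left out genes without counts was not examined, so a missing symbol was not read as absence of expression either.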

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

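The counts of gene symbols were recomputed with alternatives chosen after seeing the data. The listed symbols found in an annotation numbered 19246 with GENCODE M21, 19061 with RefSeq symbols and 20237 (99.5%) with RefSeq symbols or synonyms. The main count already accepted the alternative symbols fixed for some members. Counting RefSeq synonyms as well moved the listed members of the fixed lists from 787 to 789, and the lists with every member listed from 25 to 27. The 10 alternatives planned before the data were examined (scaling, filters, thresholds, prior count, list matching and thinning) were not run, because the values of columns not matched to a sample were not used. No paired analysis was possible because each line has 1 library and no column was assigned to a line.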

Other observations

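Of the 8 members of the fixed lists whose symbols were not listed, Colgalt1, which encodes a collagen galactosyltransferase, stood under its older symbol Glt25d1, and Ifit3b, an interferon-induced gene, under I830012O16Rik. The others were Btnl8, Vgll1 and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. Xist, which the rule named together with these Y-linked genes, was listed. Of 256 RefSeq protein-coding genes on chromosome Y, 1 (Uba1y) had a listed symbol or synonym, against 726 of 966 (75.2%) on chromosome X. On the autosomes the share ran from 72.6% (chromosome 7) to 95.3% (chromosome 3), with 1484 of 1609 (92.2%) on chromosome 11. Most of the 256 Y genes carry Gm model names, so their share is not directly comparable with the others. Among the Y genes with other names, Uba1y was still the only one listed. Zfy1, Zfy2, Usp9y and Sry, for example, were not. None of the 13 mitochondrial protein-coding genes had a listed symbol or synonym by their RefSeq names. GENCODE names were not compared by chromosome, so a listing under another name was not excluded. The levels of Y-linked and mitochondrial transcripts, like those of all other genes, were not analysed here, and the sex of the animals behind the lines was not examined.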
